A study of Gallus gallus with 48 samples.

How the data were processed

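The series holds 48 expression arrays from 24 White Leghorn chicks. At 1 week of age each bird had a spectacle lens fixed over 1 eye, of either -15 or +15 diopters (D), for 6 hours or 3 days, and the other eye served as its control. A negative lens moves the image behind the retina and a positive lens moves it in front. The 4 conditions had 6 birds each, which gives 8 groups of 6 arrays. Retina and retinal pigment epithelium (RPE) were collected as 1 sample. Per the labels' protocols, 100 ng of total RNA was amplified and labelled as biotinylated cDNA with a NuGEN Ovation kit and hybridised to the Affymetrix Chicken array. The birds were kept on a cycle of 12 hours of light per day, and the time of day of collection is not given in the sources used here.

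The deposited values are log2 signals per probe set. The authors made them with RMA, which corrects background, normalizes the probe intensities of all arrays to one distribution and summarises the probes of each probe set, and they also used Partek, per the submitters' processing notes. Versions and settings are not given in the sources used here. The values ran from 1.88 to 14.8, and the array medians lay between 6.39 and 6.51. RMA forces the arrays to share a distribution, so a shift of most genes in one direction would not be seen. It also compresses differences between dim signals. Arrays carry no read counts, and their number limits the precision.

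The table held 38535 probe sets. The 153 Affymetrix control and reporter probe sets were left out of the tests, so 38382 were tested in every comparison with no filter on signal. The platform annotation named 1 gene for 27168 of these, several for 177 and none for 11037. No gene was named from a probe set with several symbols. The 13009 genes were each represented, where 1 value per gene was needed, by the probe set with the highest mean over all arrays. The 541 probe sets for viral sequences served as a measure of background, and their 95th percentile was 4.50 log2. A total of 8295 tested probe sets had a mean below it. No 2 arrays were identical, and the correlation of any 2 arrays over all probe sets lay between 0.952 and 0.997.

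Lens and control eyes were paired by the bird number in the sample titles, which marks 2 eyes of the same animal. As a check, the deviations of the 2 eyes from their group means were correlated for each bird. The correlation exceeded 0.1 in 20 of 24 birds, with a median of 0.42 and a range from -0.23 to 0.85. The main test was limma's lmFit and eBayes (limma 3.58.1 in R 4.3.3) on all 48 arrays with the bird as a block. This amounts to a fit of 24 within-bird differences with 20 residual degrees of freedom, and the 4 conditions share 1 estimate of the spread. The block was chosen because the series compares the 2 eyes of the same birds. The series text names only an analysis of variance and does not say whether it used the bird, so the fit without the block is reported as an alternative. P values are two-sided and were adjusted by Benjamini-Hochberg over the probe sets tested, with a threshold of 0.05. "Rose" and "fell" are used only of results past that threshold, or past it over a list alone where so stated. The sign of a value that did not pass is not read as a direction.

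The lens comparisons were 4, with 1 per condition. A further 4 interaction contrasts of the same fit asked whether the lens effect differed between lens powers or durations. The control eyes alone were compared between 3 days and 6 hours, with 12 arrays at each time. The mean lens effects of 2 conditions were correlated across probe sets, with p values from all 4096 ways of flipping whole birds, and probe sets are not independent replicates. Exact tests on 6 birds used all 64 sign patterns and cannot give a p below 0.03125.

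A total of 24 gene lists were fixed: circadian clock and melatonin, activity-dependent immediate early genes, retinal neuropeptides, dopamine and other transmitter signalling, BMP and TGF-beta signalling, retinoic acid, growth factors, extracellular matrix, rod phototransduction, cone phototransduction, RPE and pigment, ion and water transport, Muller glia, other retinal neurons, choroid and sclera, vessels and muscle, blood and immune cells, lens and anterior segment, heat shock, glycolysis and hypoxia, sterol synthesis, interferon response, oxidative phosphorylation and cytosolic ribosomal proteins. The last 2 hold every measured gene of their families. Lists were tested with camera at a preset correlation of 0.01 between genes and adjusted over the 24 lists of a comparison. Camera with an estimated correlation and fry, which asks whether a list moves one way without comparing it with other genes, were alternatives. For the control eyes, the share of list members called was compared with that of all other genes by Fisher's exact test, adjusted over the lists. List differences between conditions were tested by exact permutation of birds.

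Genes were named by rule. In each lens comparison the rule took up to 12 rises and 12 falls, with the largest change among probe sets past the threshold and of the same sign in at least 5 birds. Where fewer than 10 genes qualified, the 10 with the lowest p were named instead. A further 12 genes studied in chick eye growth (EGR1, VIP, GCG, PENK, BMP2, TGFB2, OPN4, TH, ALDH1A2, PER2, CRY1 and NOS1) are reported in every condition, with p also adjusted over these 12 alone. For lists the rule took up to 4 members past the threshold, for interactions up to 8 probe sets past the threshold or the 3 with the lowest p, and for control eyes 10 rises and 10 falls. The tests, lists, naming rule and other settings were fixed before the data were examined. The other settings were no replicate block, the bird as a random effect, only the arrays compared, probe sets above the median only, a second quantile normalization, median centring, a trended robust prior, array weights, an analysis of variance per probe set without moderation, a threshold of 0.10 and leaving out each bird. Others, and 2 comparisons pooled over conditions, were chosen after seeing the data and are marked so in the closing section.

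The fits were tested on simulated data with the real means and spreads and known changes. At a log2 change of 0.6, the share of changed probe sets recovered among 38382 was 88.1% for -15 D at 6 hours, 85.1% for +15 D at 6 hours, 91.0% for -15 D at 3 days, 80.6% for +15 D at 3 days and 91.0% for the control eyes. At a change of 0.3 these shares were 41.8%, 25.4%, 29.9%, 20.9% and 46.3%. Each simulated comparison held 67 probe sets changed by 0.3, 67 by 0.6 and 66 by 1. So many changes ease the Benjamini-Hochberg cutoff, whereas the real lens comparisons called 15, 3, 27 and 2 probe sets. The simulated spread was also the same in every bird. The shares recovered can thus be lower in the real data. A difference of 1 between lens effects was recovered in 97.0%, 95.5%, 94.7% and 96.2% of probe sets for the 4 interactions. In the list test, simulated for -15 D at 6 hours, 3 of 3 lists shifted by -0.2 log2 were recovered, with 0 false calls. That shift is larger than most of the list means reported here, and smaller shifts were not simulated. The simulated noise was independent between genes, so it does not show how camera calls lists of correlated genes. Swapping eyes in the real data of this condition called up to 17 lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.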

Results

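The retina and pigment epithelium of eyes behind a lens were compared with the same birds' open eyes. With the bird as block in 24 chicks, limma called 15 of 38382 probe sets after 6 hours of a -15 D lens, 3 after 6 hours of a +15 D lens, 27 after 3 days of -15 D and 2 after 3 days of +15 D. DUSP4, a phosphatase that switches off MAP kinases and is itself induced by their activity, fell in 3 of the 4 conditions. Without the replicate block the counts were 0, 0, 0 and 2, so all but DUSP4 after 3 days of +15 D rest on the pairing of eyes. At unadjusted p<0.05 there were 3885, 2883, 5457 and 1505 probe sets, against 1919.1 expected by chance. An excess of this kind does not show lens effects. Between the 2 sets of untreated control eyes the count was 5030 at 6 hours and 1504 at 3 days, with 0 called at either time. Those are unpaired comparisons of different birds, so they show how far such counts vary but are no baseline for the paired eyes. In the untreated control eyes, 791 probe sets differed between birds at 3 days and at 6 hours (5400 at unadjusted p<0.05), in a comparison of 12 with 12 eyes that is not on the same footing as the pairs of 6.

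After 6 hours of a -15 D lens, a retinal neuropeptide was lower in the lens eye and an inhibitor of bone morphogenetic proteins was higher. VIP, the peptide of a class of amacrine cells that has been tied to eye growth in chicks, fell. NOG, which encodes the secreted BMP antagonist noggin, was the only probe set that rose. Of the 15 probe sets called, 14 fell, and they named 12 genes. Array weights gave 296 (19 up, 277 down) and probe sets above the median 102 (3 up, 99 down). The actin 3'/5' signal ratio, a measure of RNA integrity, was lower in 6 of 6 lens eyes (-0.16, SD 0.20, exact p = 0.03125, adjusted p = 0.208), but the same ratio of GAPDH was not (0.021, above 0 in 4 of 6 birds, exact p = 0.469). With the actin ratio as a covariate, chosen after the values were seen, 1 probe set was called.

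VIP fell by 0.73 log2 in all 6 birds (1.66 times lower, SD 0.32, limma adjusted p = 0.00358), from 10.54 in control to 9.81 in lens eyes. NOG rose by 0.76 in all 6 birds (1.70 times higher, SD 0.47, adjusted p = 0.0293). The rise was 1.67 in bird 3 and between 0.40 and 0.76 in the others. SNAP25, a protein of the complex that fuses synaptic vesicles, changed by -0.74 (SD 0.28, adjusted p = 0.0293). UNC13A, which primes vesicles for release, changed by -0.55 (0.0489) and RAB3GAP2, a regulator of the vesicle protein Rab3, by -0.36 (0.0293). ADCY1, the calcium-activated adenylyl cyclase of neurons, changed by -0.65 (0.0293), PDE3A, which breaks down cyclic nucleotides, by -0.51 (0.0293) and GRM5, a metabotropic glutamate receptor, by -0.51 (0.0293). EPHB6, an ephrin receptor without kinase activity, changed by -0.50 (0.0293), the adaptor of immune receptors TRAF3 by -0.52 (0.0434), the photoreceptor motor protein MYO3A by -0.42 (0.0489) and the splicing factor SCAF11 by -0.37 (0.0489). All fell in 6 of 6 birds except MYO3A, which fell in 5.

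The probe sets called for these genes were often not the brightest for the gene. Of the 12 genes, 10 had a brighter probe set, 0 of these passed, and all 10 had the same sign with a median size of 0.31 against 0.51. This comparison was chosen after the values were seen. In the lens eyes the called probe sets of UNC13A (4.15), GRM5 (4.47) and EPHB6 (4.11) were below the background of 4.50, so the size of their falls is uncertain. That of ADCY1 was below it over all arrays (4.33), while its brightest changed by -0.40 (adjusted p = 0.0615). The brightest for SNAP25, at a mean of 13.8, changed by only -0.042. VIP and NOG had a single probe set. Leaving out bird 3 left 0 calls and put VIP at an adjusted p of 0.0503. Leaving out bird 1 left 1 call, bird 4 or bird 5 left 2, and bird 6 left 8.

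Of the other genes studied in chick eye growth, none passed over all probe sets. Over these 12 genes alone, VIP (1.12e-06), the retinal growth regulator BMP2 (-0.86, SD 0.89, 5 of 6 birds, 0.0106) and the light receptor of inner retinal neurons OPN4 (-0.38, SD 0.28, 5 of 6 birds, 0.0106) passed, with limma adjusted p over all probe sets of 0.177 for BMP2 and 0.172 for OPN4. The differences that did not pass were -0.17 for the transcription factor EGR1, -0.20 for the glucagon gene GCG, 0.015 for the enkephalin precursor PENK, 0.22 for the growth factor TGFB2, -0.082 for the dopamine-synthesizing enzyme TH, 0.85 (SD 2.54) for the retinoic acid enzyme ALDH1A2, -0.26 and -0.019 for the clock genes PER2 and CRY1 and -0.048 for the nitric oxide synthase NOS1.

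Clock and melatonin genes were lower as a group after 6 hours of -15 D, and bird 3 carried much of the change. Of the 24 lists, 11 were called by camera, 8 up and 3 down, but 0 with an estimated correlation and 0 by fry. The clock and melatonin list had 21 of 26 members below 0 (mean -0.11, camera adjusted p = 0.00014, adjusted p = 0.563 with an estimated correlation), and its mean was below 0 in 6 of 6 birds (exact p = 0.03125). Bird 3 lay at -0.32 and the others between -0.09 and -0.03, and without it the mean was -0.068 (adjusted p = 0.0371). No member passed over all probe sets. Adjusted over the list alone 6 fell: the melatonin receptors MTNR1A (-0.31) and MTNR1B (-0.27), the clock activator CLOCK (-0.22), the clock repressor PER3 (-0.33), OPN4 (-0.38) and the related OPN4-1 (-0.35). Transmitter genes for dopamine, acetylcholine, GABA and glycine were lower (mean -0.063, 0.00269, 0.563 estimated, 0 of 38 members over all probe sets and 0 over the list alone, lower in 5 of 6 birds), but not without bird 3 (-0.034, 0.269).

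Lists of other tissues and of basic cell functions were called too, most of them because of 1 bird. Lens and anterior segment genes were lower (mean -0.81, camera adjusted p = 0.00269, 0.563 with an estimated correlation), with bird 5 at -3.48 and bird 3 at -1.35. The mean was -0.27 without bird 5 (0.529) and -0.0034 without the 3 birds whose eyes differed widely (0.990). Genes higher as lists were those of RPE and pigment (0.20, 0.00305, 0.610), vessels and muscle (0.33, 0.0299, 0.610), blood and immune cells (0.32, 0.00242, 0.610), interferon response (0.47, 0.00014, 0.605), BMP and TGF-beta signalling (0.086, 0.0118, 0.563) and growth factors (0.11, 0.0443, 0.563), with the same order of mean, camera adjusted p and adjusted p with an estimated correlation. RPE genes were above 0 in 5 of 6 birds and the other 5 lists in 3 of 6. Bird 3 was at 1.31 for RPE, 1.81 for vessels and muscle, 1.82 for blood, 2.49 for interferon, 0.61 for BMP and 0.69 for growth factors, and at 2.25 for the choroid list. Without bird 3 none of the 6 lists passed, with means of -0.015, 0.036, 0.023, 0.061, -0.020 and -0.0083 (adjusted p of at least 0.938). Growth factors also did not pass without bird 1 (0.0808), nor vessels and muscle without bird 4 (0.133). Energy genes were higher as a list by a mean of 0.050 (oxidative phosphorylation, 68 of 78 members above 0, 8.03e-06, 0.563 estimated), and ribosomal proteins by 0.042 (66 of 67 above 0, 6.19e-06, 0.563 estimated). Of all these members only NOG passed over all probe sets, and it was also the only one past the threshold adjusted over its list alone. With the eyes of some birds swapped, 15 of 32 arrangements, the real one included, gave as many list calls, with up to 17 lists called. The list count is thus not separable from chance. Over their lists alone BDNF, a neurotrophin induced by activity (-0.33), DUSP4 (-0.43, adjusted p = 0.0595 over all probe sets, lower in 5 of 6 birds), the PACAP receptor ADCYAP1R1 (-0.32) and the potassium channel KCNMA1 (-0.20) also fell, each in a list that was not called.

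After 6 hours of a +15 D lens, a regulator of MAP kinase signalling and an enhancer of WNT signalling were lower in the lens eye, and activity-induced genes were lower as a group. DUSP4 carried both of the other called probe sets. The number of calls was small, at 3 of 38382, all down, with 2883 at unadjusted p<0.05.

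DUSP4 fell by 0.57 log2 in all 6 birds (SD 0.08, limma adjusted p = 0.0343), and its second probe set, the brighter one, fell by 0.52 (0.0343). Another probe set, with a mean of 2.98 below background, did not change. RSPO2, a secreted activator of WNT signalling, fell by 0.50 in all 6 birds (SD 0.21, 0.0343). The calls did not survive the loss of single birds: 0 probe sets passed without bird 1, 3, 4 or 6 and 1 without bird 2 or bird 5. RSPO2 passed only without bird 2 (adjusted p = 0.0254), and DUSP4 passed in no omission. The other genes with the lowest p did not pass, each with the same sign in 6 of 6 birds: the amylase AMY1A (-0.18), PDE3A (-0.36, adjusted p = 0.0767), VIP (-0.46, 0.382, 0.000928 over the 12 named genes), BMP4, a growth factor of eye development (0.61, 0.382), the muscle protein MYPN (-0.38), the collagen receptor DDR2 (0.32), the desmosome protein PKP1 (0.33) and the collagen chaperone FKBP14 (-0.45). DDR2, at a mean of 4.32, was below background. Over the 12 named genes alone EGR1 (-0.38, 5 of 6 birds, 0.00557) and OPN4 (-0.30, 0.0457) also passed. BMP2, at 0.52 (SD 0.58, 5 of 6 birds, 0.149), did not. The remaining differences were 0.035 for GCG, 0.033 for PENK, 0.23 for TGFB2, -0.11 for TH, 0.092 for ALDH1A2, 0.060 for PER2, 0.0043 for CRY1 and 0.039 for NOS1.

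Activity-dependent immediate early genes fell as a list after 6 hours of +15 D (mean -0.098, camera adjusted p = 0.000363, 0.0232 with an estimated correlation, fry 0.00245), with 19 of 25 members and 4 of 6 birds below 0 (exact p = 0.125). It did not pass with probe sets above the median only (mean -0.059, adjusted p = 0.0548), and its mean was -0.061 without bird 1 (0.00212). Only DUSP4 passed over all probe sets. Adjusted over the list alone, EGR1, DUSP4, the synaptic plasticity gene ARC (-0.65), BDNF (-0.25) and the transcription factor MAFF (-0.22) fell. ARC was below background in the lens eyes (4.14). Over the neuropeptide list alone VIP fell. Markers of ganglion, amacrine, bipolar and horizontal cells were higher as a list (mean 0.062, 0.0143, 0.972 with an estimated correlation, 23 of 28 above 0, 0 members over all probe sets and 0 over the list alone), but not without bird 1 (0.026, 0.293) or bird 4 (0.062, 0.0522). Of 24 lists, 2 were called, and 16 of 32 arrangements of eyes, the real one included, gave as many, with up to 12.

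After 3 days of a -15 D lens, the activity-dependent transcripts EGR1 and DUSP4 were lower in the lens eye. The largest falls were those of a phosphatase subunit, PPP2R2A, and a phospholipase, PLA2G10L, and the lowest p was that of the ubiquitin ligase RNF149. Of 27 probe sets, 7 rose and 20 fell, and they named 20 genes. The lens eyes of this condition also had a higher actin 3'/5' signal ratio, by 0.32 log2 in 6 of 6 birds (SD 0.14, exact p = 0.03125, adjusted p = 0.208), which is a sign of RNA degradation, and the GAPDH ratio was higher by 0.098 in 6 of 6 birds (exact p = 0.03125, adjusted p = 0.208). Their vessel and muscle genes had a mean difference of 0.61 in 5 of 6 birds (exact p = 0.0625, adjusted p = 0.3125, camera adjusted p = 0.534 with an estimated correlation). With the arrays centred to one median, 3 probe sets were called, 0 up and 3 down, fewer than the 17 for 6 hours of -15 D. With the actin ratio as a covariate, chosen after the values were seen, 2 were called, fewer than the 3 for 3 days of +15 D. Other settings gave far more, with 656 from only the arrays compared, 2284 with array weights, 381 above the median and 233 without the wide birds.

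RNF149, a ubiquitin ligase, changed by -0.52 (SD 0.12, adjusted p = 0.000757), DUSP4 by -0.62 (SD 0.16, 0.0025) and PPP2R2A, a regulatory subunit of protein phosphatase 2A, by -0.74 (SD 0.28, 0.0025), each in 6 of 6 birds and each past the threshold on leaving out any bird. EGR1, the transcription factor by which glucagon amacrine cells respond to the sign of defocus, fell by 0.66 (SD 0.32, 0.0482, 6 of 6 birds), while its brighter probe set changed by -0.37 (0.0923). The phospholipase PLA2G10L changed by -0.74 (SD 0.21, 0.0445), the vesicle protein SYN2 by -0.61 (SD 0.17, 0.0482), the ubiquitin ligase adaptors KLHL5 by -0.60 (0.0482) and FBXO33 by -0.50 (0.0445), the receptor kinase adaptor SHC4 by -0.52 (0.0445), the palmitoyl transferase ZDHHC12 by -0.52 (0.0482), EIF4E, which brings mRNA caps to the ribosome, by -0.52 (0.0445), and the lysosomal transporter SLC15A4 by -0.46 (0.0482). Rises were seen for the small GTPase RASL10A (0.43, SD 0.15, 0.0445), the nucleotidase ENTPD7 (0.34, 0.0482), and GMPPA, an enzyme subunit of sugar nucleotide supply (0.32, 0.0482). These genes moved the same way in 6 of 6 birds. ZDHHC12 was below background in the lens eyes (4.15).

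Of the 20 named genes, 11 had a brighter probe set, none of these 11 passed and 9 had the same sign, with a median size of 0.095 against 0.52. This comparison was chosen after the values were seen. The brightest for PPP2R2A changed by 0.14 (adjusted p = 0.107), for RNF149 by -0.12 (0.271) and for EIF4E by -0.21. Leaving out 1 bird left between 3 and 6 calls, the highest without bird 1, and each of birds 3, 4, 5 and 6 left 3. BMP2 changed by -1.15 in 6 of 6 birds (SD 0.55) and did not pass over all probe sets (adjusted p = 0.0655), but did over the 12 named genes (0.00182). GCG changed by -0.40 in 5 of 6 birds (0.108, 0.00811 over the 12). The other named genes did not pass: VIP -0.083, OPN4 -0.25, PER2 -0.20, TGFB2 -0.077, PENK 0.052, TH -0.024, ALDH1A2 -0.13, CRY1 -0.0014 and NOS1 -0.024.

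Among lists after 3 days of -15 D, immediate early genes fell most clearly (mean -0.099, camera adjusted p = 8.91e-05, 0.0168 with an estimated correlation, fry 0.00568), with 17 of 25 members below 0 and 6 of 6 birds below 0 (exact p = 0.03125). By the brightest probe set of each gene, which the list tests use, only DUSP4 passed over all probe sets. EGR1 passed by its dimmer probe set, as given above. Adjusted over the list alone ARC (-0.47), EGR1, DUSP4, BDNF (-0.25) and the signalling kinase SIK1 (-0.22) fell, and the transcription factor JUN rose (0.19). Another BDNF probe set, the one called when the conditions were pooled, changed by -0.13. A total of 8 of 24 lists were called, 2 up and 6 down. Of 32 arrangements of eyes, the real one included, 4 gave as many, with up to 9. Falls in clock (mean -0.060, camera 0.0194, 0.534 with an estimated correlation), transmitter (-0.057, 0.00601, 0.534), rod phototransduction (-0.088, 0.0212, 0.537), ion and water transport (-0.025, 0.0299, 0.395) and lens and anterior segment lists (-0.49, 0.0379, 0.655) were not called with an estimated correlation. The last was 1 bird: bird 4 lay at -3.03, 4 of 6 birds were above 0, and the mean without bird 4 was 0.012 (0.683). Ion and water transport was at 0.023 without bird 5 (0.106) and rod phototransduction did not pass without bird 2 (0.0554) or bird 5 (0.106). No member of these passed over all probe sets, and over the lists alone only the clock activator NPAS2 (-0.41) and the rod phosphodiesterase PDE6B (-0.43) fell.

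Vessel and muscle genes were higher (mean 0.61, SD 0.72, 5 of 6 birds, exact p = 0.0625, camera 0.000483, 0.534 with an estimated correlation), with a mean of 0.38 without bird 6. Of the 28 members 26 were above 0. Over the list alone 9 rose, with the largest changes in the troponins TNNC2 (2.15, SD 3.27) and TNNT3 (2.05), the light chain MYL1 (2.12) and the actin ACTA1 (1.70, SD 2.32), and 0 passed over all probe sets. TNNC2 and MYL1 were below background in the control eyes. Oxidative phosphorylation genes were higher (mean 0.068, 8.91e-05, 0.534 estimated, 6 of 6 birds, exact p = 0.03125, mean 0.045 without bird 1, NDUFS5 0.32 over the list alone). Heat shock genes passed by fry alone (mean 0.052, fry 0.0296, camera 0.210, 6 of 6 birds), with HSP90AB1 (0.25) and CDKN1A (0.30) past the threshold over the list alone. In lists that were not called, members past the threshold over their list alone were NOG (0.47), BMP2 and the activin antagonist FST (-0.28), the secreted signal WNT5A (0.29), the cartilage protein COMP (0.55), the oxygen sensor EGLN3 (-0.54) and the sterol and fatty acid enzymes NSDHL (0.32), HSD17B7 (0.25), SQLE (0.22), LSS (0.16) and FADS2 (-0.26).

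After 3 days of a +15 D lens, DUSP4 was the only gene that passed, and activity-induced genes fell as a group. Both called DUSP4 probe sets were lower in all 6 birds. The list of immediate early genes gave its lowest p here. The number of calls was 2 of 38382, both down, with 1505 at unadjusted p<0.05, fewer than the 1919.1 expected by chance.

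DUSP4 fell by 0.79 log2 in 6 of 6 birds (SD 0.25, limma adjusted p = 0.000102), and its second probe set fell by 0.72 (0.00108). It stayed past the threshold without any 1 bird, and the 2 probe sets were still called without the replicate block. No probe set was called with only the arrays compared, with a trended robust prior or without moderation. The other genes with the lowest p did not pass: the ubiquitin ligase component ASB18 (-0.62), the prolactin-like hormone PRLL (0.97, 5 of 6 birds), EGR1 (-0.69) and ARC (-0.82), all with an adjusted p of 0.110, the serine protease PRSS56, whose human form is tied to eye size (-0.63, 0.124), the urotensin peptide UTS2B (-0.72), the centromere protein OIP5 (-0.24, 0.168), the dopamine receptor DRD2 (-0.37) and BDNF (-0.35, 0.204). Over the 12 named genes alone VIP (-0.36, 5 of 6 birds, 0.00648, 0.776 over all probe sets) and the brighter probe set of EGR1 (-0.41, 0.00519) passed. The other differences were -0.019 for BMP2 (SD 0.60), -0.13 for GCG, -0.20 for OPN4, -0.067 for TGFB2, 0.021 for PENK, -0.15 for TH, -0.23 for ALDH1A2, 0.23 for PER2, -0.024 for CRY1 and 0.018 for NOS1.

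The immediate early list fell after 3 days of +15 D (mean -0.16, camera adjusted p = 2.01e-11, 7.39e-05 with an estimated correlation, fry 3.83e-05), with 20 of 25 members and 5 of 6 birds below 0 (exact p = 0.0625). DUSP4 alone passed over all probe sets, and over the list alone DUSP4, ARC, EGR1, MAFF (-0.24), the transcription factor FOSL2 (-0.26) and the growth inhibitor BTG2 (-0.15) fell. FOSL2 was below background in both eyes and ARC in the lens eyes (4.21). Lens and anterior segment genes were lower (mean -0.80, 0.000128, 0.750 with an estimated correlation) and ribosomal proteins higher (0.026, 2.11e-06, 0.750, 54 of 67 above 0), with 0 members past the threshold over all probe sets and 0 over the lists alone. Bird 3 lay at -3.05 for the lens and anterior segment list, which did not pass without it (-0.34, 0.503), and the ribosomal mean was 0.015 without bird 5. A total of 3 lists were called, and 30 of 32 arrangements of eyes, the real one included, gave as many, with up to 16. Leaving out bird 1, 4 or 5 raised the number to 10, 10 and 11. VIP and the growth factor FGF1 (-0.22) fell over their own lists alone.

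**Figure D1:**
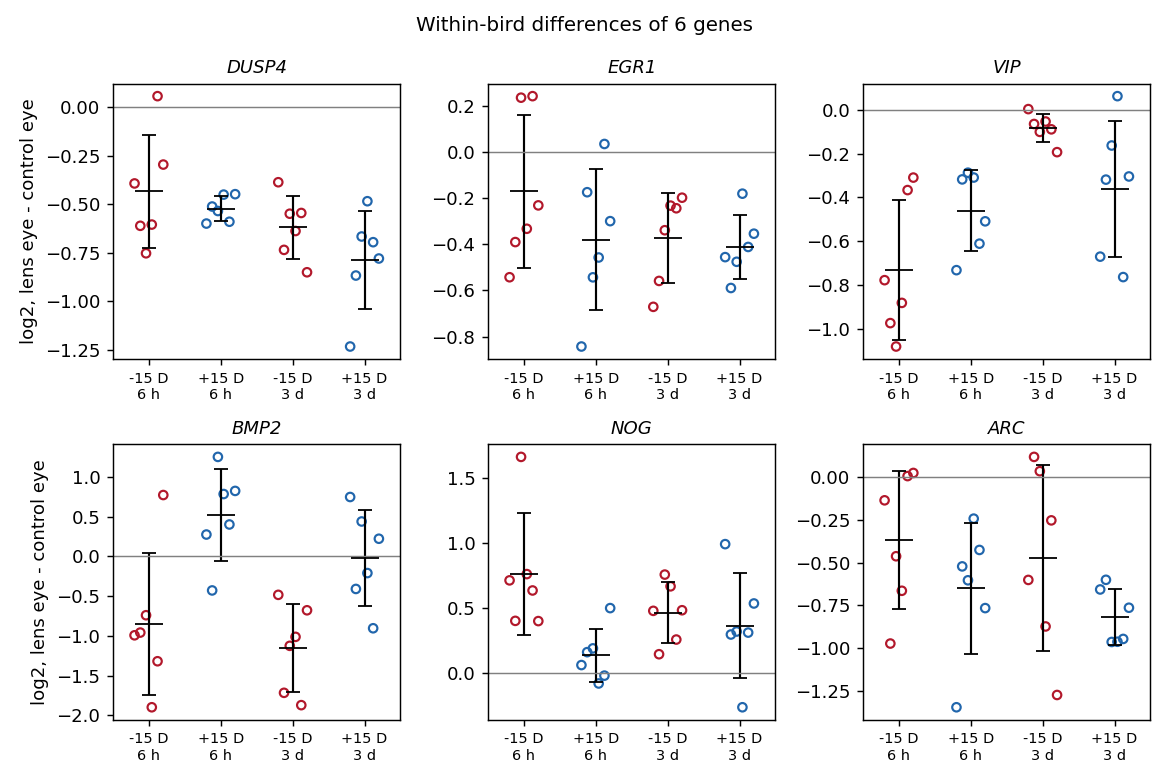
Lens eye minus control eye (log2) in the 4 conditions for DUSP4, EGR1, VIP, BMP2, NOG and ARC; open dots are birds, bars are means and error bars are SD (red, -15 D, blue, +15 D). DUSP4 lay at -0.62 in the -15 D and -0.79 in the +15 D eyes after 3 days.

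**Figure D2:**
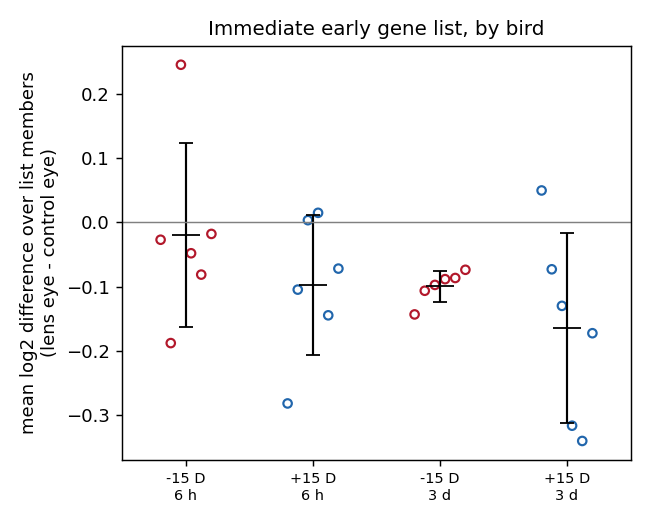
Mean log2 difference of the immediate early list, lens eye minus control eye, for each bird in the 4 conditions; dots are birds, bars are means and error bars are SD. The means were -0.020, -0.098, -0.099 and -0.16.

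Lists that passed in no lens comparison by camera were those of neuropeptides (adjusted p in the order -15 D 6 hours, +15 D 6 hours, -15 D 3 days, +15 D 3 days: 0.493, 0.825, 0.122 and 0.0782), retinoic acid (0.199, 0.927, 0.320 and 0.714), extracellular matrix (0.106, 0.884, 0.405 and 0.714), cone phototransduction (0.473, 0.160, 0.405 and 0.714), Muller glia (0.432, 0.313, 0.525 and 0.764), choroid and sclera (0.0680, 0.825, 0.541 and 0.834), heat shock (0.425, 0.295, 0.210 and 0.486), glycolysis and hypoxia (0.499, 0.313, 0.0868 and 0.764) and sterol synthesis (0.569, 0.825, 0.405 and 0.539). The genes past the threshold over these lists alone are given above.

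Whether the lens effect depended on the lens sign or on time was asked directly. The sign of the lens called no gene at either duration. BMP2 was the studied gene that differed most: -15 D minus +15 D was -1.37 at 6 hours (SE 0.36, limma adjusted p = 0.985 over all probe sets, 0.0104 over the 12 named genes) and -1.13 at 3 days (SE 0.36, 0.411, 0.0549 over the 12). The effect of the -15 D lens differed with time in 4 probe sets, but in 0 without the replicate block, with the bird as a random effect, without moderation, or with the actin ratio or the tissue lists as covariates. Both covariate fits were chosen after the values were seen. The actin ratio itself moved with this contrast, at -0.16 in 6 hour and 0.32 in 3 day lens eyes, with the same sign in 6 of 6 birds each, while the GAPDH ratio was at 0.021 (4 of 6 birds above 0) and 0.098 (6 of 6).

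Between -15 D and +15 D limma called 0 probe sets at 6 hours (1362 at unadjusted p<0.05, smallest adjusted p = 0.985) and 0 at 3 days (3556, 0.382). The lowest p belonged to FKBP14 (0.59), the sperm protein SPATA17 (0.39) and ADCY1 (-0.64) at 6 hours, and to PPP2R2A (-0.79), PLA2G10L (-0.91) and the yolk protein VTG2 (-0.51) at 3 days. The probe sets of ADCY1 (mean 4.33) and VTG2 (mean 4.24) lay below background. Between 3 days and 6 hours of -15 D, 4 passed: RNF149 (-0.62, SE 0.09, -0.52 at 3 days and 0.10 at 6 hours, adjusted p = 0.0121), EPHB6 (0.75, SE 0.12, 0.25 and -0.50, 0.0261) and 2 probe sets without a gene name (0.67 with 0.0418, and 0.54 with 0.0423). Leaving out 1 bird left 0 to 3 of them, and RNF149 passed in 8 of the 12 omissions. The EPHB6 probe set (mean 4.66) lay below background in the 6 hour lens eyes. Its brighter probe set (mean 9.65) changed there by -0.17 (limma adjusted p = 0.449). The brighter probe set of RNF149 changed by -0.12 at 3 days (0.271). VIP, at 0.65 (SE 0.14, 0.247), passed over the 12 named genes only (0.000989). For +15 D, 0 differed with time (1332 at unadjusted p<0.05, smallest adjusted p = 1), with PKP1 (-0.53), the matrix protein SNED1 (-0.39) and OIP5 (-0.30) lowest. SNED1 (mean 3.58) lay below background and PKP1 (mean 4.50) at it. No list differed between conditions, the lowest being oxidative phosphorylation between the lens signs at 3 days (exact p = 0.026, adjusted p = 0.623).

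The mean effects of the lens on 38382 probe sets were correlated between conditions at r = 0.24 for -15 D and +15 D at 6 hours (permutation p = 0.406), 0.0012 for -15 D and +15 D at 3 days (0.992), 0.24 for the 2 durations of -15 D (0.216) and 0.22 for the 2 durations of +15 D (0.386). None lay beyond the 95th percentile of |r| over flips, which was 0.476, 0.356, 0.341 and 0.429. Spearman rho was 0.276, -0.038, 0.146 and 0.187.

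The control eyes of birds taken at 3 days and at 6 hours differed in the circadian clock and in phototransduction. Repressors of the clock, PER3 and PER2, were higher at 3 days, and the activator ARNTL (BMAL1) and the repressor NFIL3 were lower. Cone and rod genes changed in both directions, the red cone opsin falling. These are other birds at a later age, and the time of day of collection is not given in the sources used here. limma called 791 probe sets, 346 up and 445 down, with 12 control eyes at each time.

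PER3 rose by 1.34 (6.51 to 7.84, SD 0.20 and 0.17, adjusted p = 6.51e-11), its brighter probe set by 1.51, and PER2 by 1.03 (0.0272). The falls were -1.22 for ARNTL (5.1e-10, second probe set -1.29), -1.12 for NFIL3 (2.57e-06) and -0.90 for TPH1, which starts melatonin synthesis. BHLHE41 (0.52), BHLHE40 (0.26), NR1D2 (0.25) and CRY2 (0.17), further repressors of the clock loop, and ASMT, which completes melatonin (0.49), rose. The clock list had 7 rises and 3 falls among 26 members over all probe sets, 8 and 5 over the list alone, and its share called, 38.5%, exceeded the 2.98% of all genes (Fisher adjusted p = 4.13e-08).

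In phototransduction the rod phosphodiesterase PDE6B rose by 1.11 (7.44 to 8.55, SD 0.48 and 0.32, 0.000182), the cone kinase GRK7 by 0.93, the cone channel subunit CNGA3 by 0.81, the cone phosphodiesterase PDE6C by 0.66, the rod fate factor NR2E3 by 0.65 and the cyclase activator GUCA1A by 0.46, while the opsin OPN1LW changed by -1.2 (12.7 to 11.5, 1.19e-05) and the rod channel subunit CNGB1 by -1.03. Members past the threshold over all probe sets were 5 up and 1 down of 15 cone genes (40%, 3.24e-05, 8 and 4 over the list alone) and 5 up and 1 down of 18 rod genes (33.3%, 7.42e-05, 10 and 2 over the list alone). Heat shock genes were 5 up and 0 down of 33 (15.2%, 0.0165, 8 and 2 over the list alone), with the chaperones HSPH1 (0.78), HSPA4L (0.38) and HSPD1 (0.23) and the factor HSF2 (0.20). The other 20 lists had a Fisher adjusted p of at least 0.239.

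The remaining large changes were rises of the ion exchanger SLC24A4 (0.97), C7orf31 (0.91), the immune receptor TNFRSF9 (0.87), the kinases NIM1K (0.85) and GAK (0.82), the cytoskeletal linker DST (1.18, adjusted p = 0.0376) and the centrosome protein PCNT (0.89, 0.0491). DST and PCNT varied widely at 6 hours (SD 1.30 and 1.11) and rose by 1.9 and 1.61 in the -15 D sets but by 0.48 and 0.18 in the +15 D sets. Falls were those of the lipolysis inhibitor G0S2 (-1.23, 6.51e-11), the retinoic acid hydroxylase CYP26A1 (-1.10), the glycogen regulator PPP1R3C (-1.04, just below background at 3 days), PRLL (-0.93) and the tetraspanin CD82 (-0.92). Smaller changes on the lists were seen in ATF3 (0.61) and EGR1 (0.59), early response factors, NPY (-0.38), TGFB3 (0.30), the retinol carrier RBP4 (0.18), the growth signals EGF (0.50) and IGFBP3 (-0.30), the pigment cell factor MITF (0.24), the glial glutamate transporter SLC1A2 (0.49), the bipolar cell genes TRPM1 (0.51) and VSX1 (-0.29), NEUROD4 (0.33, below background), the hypoxia and glycolysis genes NDRG1 (-0.44) and PFKFB3 (-0.29) and the sterol sensor INSIG2 (0.29).

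The count depended on which birds were compared. The 4 pairings of single sets gave 469, 115, 320 and 49 probe sets, and leaving out 1 control eye gave between 510 (-15 D 6 hours, bird 4) and 1343 (-15 D 6 hours, bird 6). Control eyes of -15 D birds and of +15 D birds differed in 0 probe sets at 6 hours (5030 at unadjusted p<0.05), 0 at 3 days (1504) and 5 over both times (3737). These 5 were chosen after the values were seen, and the first 3 lie below background, so that they are not shown to be expressed: the mechanical channel PIEZO2 (-0.39, mean 3.25), the membrane traffic gene DENND1A (-0.36, mean 2.74), a probe set without a gene name (0.45, mean 4.46), the phosphatase PTPDC1 (-0.41) and another unnamed one (0.34).

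**Figure D3:**
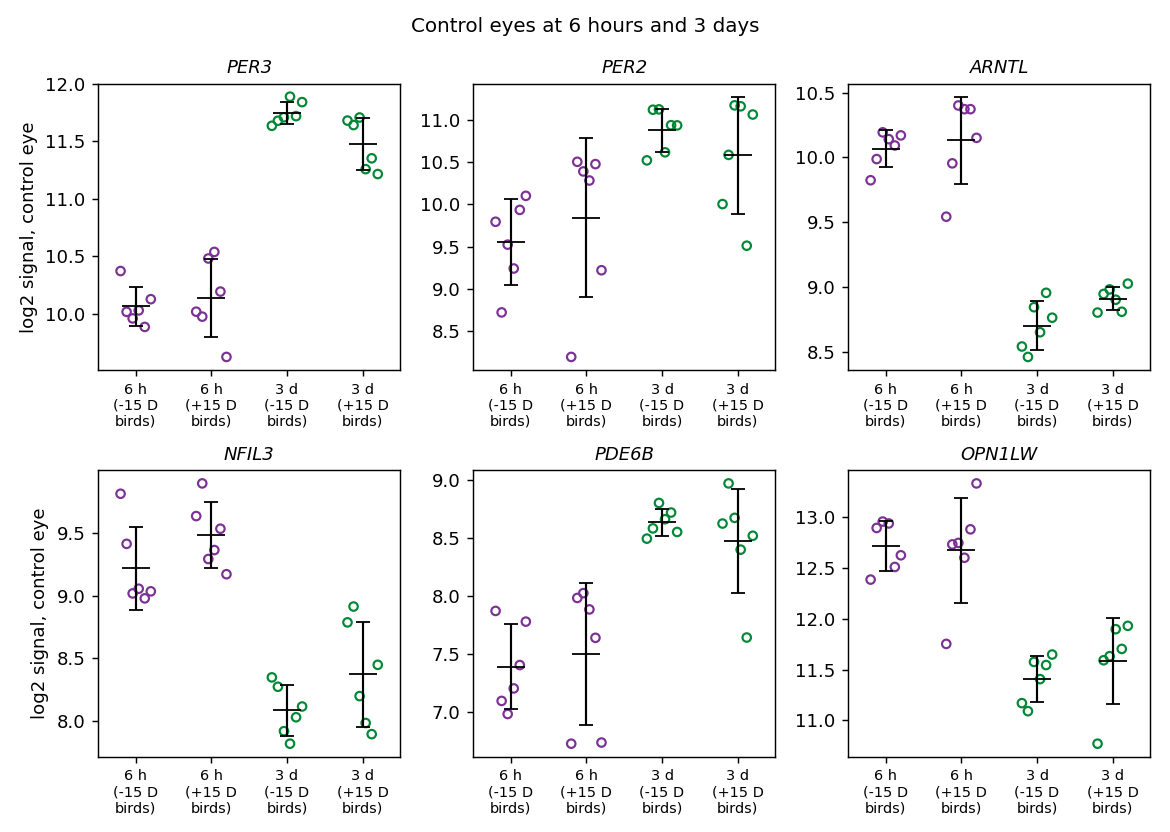
Log2 signal of PER3, PER2, ARNTL, NFIL3, PDE6B and OPN1LW in control eyes of the 4 bird sets; dots are eyes, bars are means and error bars are SD (purple, 6 hours, green, 3 days). The brighter PER3 probe set rose by 1.51 and the brighter ARNTL probe set fell by 1.29 in the 3 day sets.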

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

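The comparison of clock arms, the covariate tests, the split tests of pooled results and the choice of the patterns below were made only after the results were seen.

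Single birds lay far from the rest in 10 of 78 gene results and in 6 of 24 list results by Dixon's ratio (past its critical value at 0.05 for 6 birds), where chance alone gives about 1 in 20. In bird 3 of -15 D at 6 hours NOG changed by 1.67 against 0.40 to 0.76 in the others (ratio 0.714), TGFB2 by 1.18 against -0.03 to 0.10 (0.892), the clock list by -0.32 against -0.09 to -0.03 (0.803), the BMP and TGF-beta list by 0.61 against -0.11 to 0.07 (0.750) and the growth factor list by 0.69 against -0.16 to 0.10 (0.687). This bird also had the widest difference between its eyes over all probe sets (SD 0.610 against a median of 0.255), so these 5 are not independent of each other. UNC13A changed by -0.92 in bird 5 of the same condition (0.656). In -15 D at 3 days the far birds were bird 4 for ENTPD7 (0.50, ratio 0.758), bird 6 for OPN4 (-0.49, 0.841), bird 5 for PER2 (-0.70, 0.726), bird 3 for NOS1 (-0.26, 0.704), bird 5 for ion and water transport (-0.26, 0.715), bird 4 for the lens and anterior segment list (-3.03 against -0.33 to 0.21, 0.833) and bird 1 for oxidative phosphorylation (0.18, 0.633). In the +15 D birds they were bird 6 for PENK at 6 hours (0.13, 0.652), bird 1 for PENK at 3 days (-0.25, 0.688) and bird 5 for OPN4 at 3 days (0.43 against -0.47 to -0.24, 0.752).

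Effects that differed between conditions by a direct test were RNF149 (-0.62), EPHB6 (0.75) and 2 probe sets without a gene name (0.67 and 0.54) between the durations of -15 D. The probe sets of RNF149 and EPHB6 were not the brightest of their genes, and that of EPHB6 lay below background in the 6 hour lens eyes. VIP (0.65) between the durations and BMP2 (-1.37) between the lens signs at 6 hours passed over the 12 named genes only. The actin 3'/5' ratio, which no planned test used, was higher in the lens eyes of -15 D at 3 days by 0.32 (0.18 to 0.51 in the 6 birds) and lower in 6 of 6 lens eyes of -15 D at 6 hours by -0.16, each with an exact p of 0.03125 and an adjusted p of 0.208. The GAPDH ratio was also higher at 3 days (0.098 in 6 of 6 birds, exact p = 0.03125) but not lower at 6 hours (0.021, exact p = 0.469), so only the 3 day difference was seen in both measures.

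For the called counts, the eyes of some birds were swapped in all 32 distinct ways. The real arrangement gave the most calls in each condition, 1 of 32: 15 against at most 0 after 6 hours of -15 D, 3 against 1 after 6 hours of +15 D, 27 against 0 after 3 days of -15 D and 2 against 1 after 3 days of +15 D. No rank below 1 of 32 is possible, and the 4 conditions were not adjusted for. The distance to the other arrangements was wider for 15 and 27 than for 3 and 2. The rank was the same in each condition, so the swaps exclude a chance assignment of eyes in none of them. Leaving out bird 3 alone took the 15 calls to 0. For lists the real counts of 11, 2, 8 and 3 were equalled or exceeded in 15, 16, 4 and 30 of 32, the real arrangement included. Other arrangements called up to 17, 12, 9 and 16 lists, so chance cannot be excluded. Arrangements that call several times the real count, as with +15 D, point to a structure of the samples whose cause was not tested. Birds were also reassigned between conditions, with 100 assignments that include the real one. The 4 calls between the durations of -15 D were reached in 1 of 100 (highest other 0), the smallest share that 100 draws can give. The count was 1 of 4 interactions split, and leaving out single birds left 0 to 3 calls. It was also 0 without the replicate block, with a random effect, without moderation and with either covariate, so chance is not excluded. For the other interactions the real count was 0, which every assignment reaches (100 of 100), so the splits test nothing, and the highest counts in other assignments were 34, 1 and 2. The 791 calls in control eyes were reached in 1 of 100 (highest other 0).

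The first pattern is the difference in clock genes between control eyes at 3 days and 6 hours. The 9 negative-arm genes had a mean change of 0.42 and the 7 positive-arm or night-phase genes -0.42 (-0.30 without the night-phase repressor NFIL3), a difference of 0.84 against a 95th percentile of 0.144 and a highest value of 0.376 in 10000 random pairs of gene sets. The changes of PER3, PER2, ARNTL and NFIL3 had been seen before this test was written, so it restates them and is no test of the hour of collection, which stays open. RNA integrity left 95% (error 5.16) and choroid, vessel and muscle content 102% (error 3.89) of the called effects, so neither is the whole cause. Age also differs between these birds, and no test here separates it from the hour.

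The second pattern is BMP2, with a lower value for -15 D than for +15 D lenses, past the threshold only over the 12 named genes at 6 hours. Over both durations the difference was -1.25 (SE 0.25, adjusted p = 0.521 over all probe sets), with exact p = 0.0130 at 6 hours and 0.00866 at 3 days (smallest possible 0.00216). A second probe set gave -1.33 and another, below background, 0.22. BMP2 is made in the pigment epithelium, and unequal amounts of it in the samples could give such a difference, but 107% (error 10.7) remained with the pigment list as covariate and 99.8% (error 8.08) with RNA integrity. Neither covariate removed the difference, and BMP2 was 1 of 12 genes looked at. The pigment list is not a clean measure of pigment epithelium. In the 3 birds whose eyes differed widely it moved with the choroid list (1.31 with 2.25, -0.74 with -0.99 and 0.75 with 1.72). Unequal amounts of pigment epithelium are thus not excluded.

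The last pattern is the larger number of calls after 3 days of -15 D, where lens eyes had a higher actin ratio and a vessel and muscle list mean of 0.61 (exact p = 0.0625, adjusted p = 0.3125, camera adjusted p = 0.534 with an estimated correlation). Slopes from the other birds explained a median of 17.0% (error 11.4) of the 27 called effects for RNA integrity and 10.2% (error 22.7) for tissue. With the actin ratio as covariate the median size went from 0.52 (SE 0.090) to 0.38 (SE 0.10), 27 of 27 kept their sign and 2 were called. With the tissue lists it was 0.47 (SE 0.101), with 27 of 27 and 3 called. Most calls thus ended through a smaller effect with a larger error, and neither explanation is excluded as a part of the effect.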

How the results depend on the processing

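Settings without the 3 birds whose eyes differed widely and those with covariates were chosen only after the results were seen, and all others were planned. Counts are given in the order -15 D 6 hours, +15 D 6 hours, -15 D 3 days and +15 D 3 days, against 15, 3, 27 and 2 as planned, and the cause of a changed result was not tested. Without the replicate block they were 0, 0, 0 and 2, with the bird as random effect (correlation 0.411) 1, 8, 15 and 10, and with only the arrays compared 0, 0, 656 and 0. Probe sets above the median gave 102, 4, 381 and 2, a second quantile normalization 12, 0, 28 and 2, median centring 17, 4, 3 and 2, a trended robust prior 0, 0, 2 and 0, array weights 296, 3, 2284 and 9, analysis without moderation 0 in each, and a threshold of 0.10 gave 187, 4, 564 and 2. Without the 3 wide birds they were 2, 3, 233 and 3, with the actin covariate 1, 0, 2 and 3, and with tissue covariates 1, 3, 3 and 4. Leaving out single birds gave 0 to 16, 0 to 1, 3 to 6 and 2 to 3. For -15 D 6 hours that was 1 without bird 1, 0 without bird 3, 2 without bird 4 or 5 and 8 without bird 6.

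For the change of the -15 D effect with time, with 4 as planned, the count was 0 without the replicate block, 0 with a random effect, 1 with only the arrays compared, 2 above the median, 3 after quantile normalization, 387 with array weights, 0 without moderation, 1 without wide birds and 0 with either covariate. Single-bird omissions gave 0 to 3. The other interactions stayed at 0 except for 1 with a random effect for +15 D with time and 1 with array weights or without bird 5 of +15 D at 3 days for the lens signs at 3 days.

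List calls, 11, 2, 8 and 3 as planned, were 0, 1, 1 and 1 with an estimated correlation, 0, 1, 2 and 1 by fry, 13, 2, 7 and 4 with the mean of all probe sets, 13, 2, 8 and 3 without the block, 10, 0, 6 and 3 above the median, 8, 2, 8 and 10 without wide birds and 7, 1, 6 and 3 with the actin covariate. Single-bird omissions gave 6 to 13, 1 to 7, 5 to 10 and 2 to 11, the extremes being bird 3 of -15 D at 6 hours (6), birds 4 (1) and 6 (7) of +15 D at 6 hours, bird 5 of -15 D at 3 days (5) and birds 1 (10), 4 (10) and 5 (11) of +15 D at 3 days. The lens and anterior segment list after 6 hours of -15 D went from a mean of -0.81 to -0.0034 (adjusted p = 0.990) without the wide birds.

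Control-eye calls, 791 as planned, were 673 with the bird set as random effect, 998 on all 48 arrays, 929 above the median, 784 after quantile normalization, 714 after median centring, 1315 at 0.10, 1129 with the 3'/5' ratios and 1157 with tissue covariates. The pairings alone gave 469 (-15 D at both times), 115 (-15 D at 3 days, +15 D at 6 hours), 320 (+15 D at 3 days, -15 D at 6 hours) and 49 (+15 D at both), and omissions of single eyes 510 to 1343. The correlations of lens effects ranged over omissions from 0.04 to 0.40, -0.13 to 0.30, 0.06 to 0.33 and 0.08 to 0.25.

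Of 392 settings of the 31 passed lens genes, 184 were unchanged, 208 were weaker and 0 changed sign, and of 186 single-bird omissions 141 were weaker. The looser threshold for the adjusted p cannot lose a passed gene, so its share of the 184 was fixed in advance. Every bird gave both eyes. Settings that alter only the block, the error, the probe sets tested or the threshold therefore leave the estimated change as it was. The sign could not change in them, so the 0 tests only the other settings. Of 168 settings of the called lists 61 were weaker and 1 was reversed. The reversed one was the lens and anterior segment list after 6 hours of -15 D, without the wide birds. DUSP4 passed in 10 of 13 settings for 3 days of either lens and in 7 of 13 for 6 hours of +15 D, with an adjusted p from 4.45e-07 to 0.909 for 3 days of +15 D. VIP at 6 hours of -15 D passed in 9 of 13, RNF149 in 11 of 13, PPP2R2A in 8 of 12, RSPO2 in 7 of 13 and NOG in 5 of 13. Each of these counts, like those of DUSP4, includes the looser threshold, at which a gene that passed as planned cannot fail.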

Other observations

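The hypothesis, the pooled comparisons and their split tests in this part were chosen only after the results were seen.

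The immediate early genes were lower in lens eyes of more than 1 condition, whichever way the lens moved the image. The hypothesis is that wearing a lens of either sign lowers activity-dependent transcription in the retina. Over 24 birds the list mean was -0.095 (SD 0.121), below 0 in 20 of 24 birds (permutation p = 0.00068 in 100000 draws). The mean was -0.060 in -15 D and -0.131 in +15 D birds, and no difference between the lens signs was found (permutation p = 0.156). The result was seen in the same birds that raised the idea, so new birds, with both eyes open or with a plano lens as a further group, would be needed to tell defocus from the presence of a lens.

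The 4 conditions were pooled to ask what any lens changes. limma called 143 of 38382 probe sets (34 up, 109 down, 93 named genes, 5171 at unadjusted p<0.05). Of 100 arrangements of eyes, only the real one gave as many (highest other 0). Without the replicate block 15 were called, all among the 143. Without the wide birds it was 69 (53 kept), with the actin ratio 193 (143 kept) and with tissue lists 135 (77 kept). The signalling genes DUSP4 (-0.59, adjusted p = 3.22e-08, 23 of 24 birds) and SHC4 (-0.32, 0.00131, 22 of 24) fell, as did the phosphodiesterases PDE3A (-0.29, 6.69e-05, 22 of 24) and PDE10A (-0.32, 0.000694, 23 of 24). Peptides and activity genes that fell were VIP (-0.41, 0.000129, 22 of 24), EGR1 (-0.52, 0.000226, 21 of 24), ARC (-0.58, 0.000628, 20 of 24), BDNF (-0.25, 0.00167, 23 of 24) and UTS2B (-0.53, 0.000694, 24 of 24). RSPO2 (-0.26, 0.00187, 20 of 24), PRSS56 (-0.37, 0.00383, 21 of 24), and the thyroid hormone enzyme DIO2 (-0.16, 0.00187, 22 of 24) also fell, and NOG rose (0.43, 0.00221, 21 of 24). OPN4 fell (-0.28, 0.0194, 21 of 24) but did not pass with the tissue lists (0.0663) or without the wide birds (0.124). Without the replicate block BDNF (0.0569), DIO2 (0.108), RSPO2 (0.103), PRSS56 (0.678), NOG (0.259) and OPN4 (0.983) did not pass. The immediate early list fell (camera adjusted p = 4.77e-08, 0.000726 with an estimated correlation), while clock (0.00107, 0.400), transmitter (0.000563, 0.400), vessel and muscle (0.000563, 0.506), lens and anterior segment (0.00074, 0.506), oxidative phosphorylation (0.00173, 0.796) and ribosomal lists (7.52e-07, 0.400) were not called with an estimated correlation. Over all probe sets, 6 of the 25 members of the immediate early list fell and 1 rose.

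Pooled by lens sign instead, limma called 0 probe sets (3451 at unadjusted p<0.05), a count that every reassignment of birds reaches (100 of 100, at most 1 call), so these splits test nothing. Camera called oxidative phosphorylation higher with -15 D (adjusted p = 2.53e-09), vessels and muscle higher (0.0390), and clock (0.0134), transmitter (0.0393), ion and water transport (0.0393) and cone lists (0.0445) lower, but none with an estimated correlation (at least 0.676). The lowest p belonged to TMEM131 (-0.38), ZRSR2 (0.40) and BMP2 (-1.25, adjusted p = 0.521). A pooled mean does not show that the conditions share a response: lens effects were correlated between the signs at r = 0.24 at 6 hours (permutation p = 0.406) and 0.0012 at 3 days (0.992), and the early list was not called after 6 hours of -15 D (camera adjusted p = 0.193). The absence of calls between the signs does not show that none exists.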
